A study of Mus musculus with 2 samples.

How the data were processed

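The series holds RNA sequencing of mouse liver in 2 libraries, 1 per genotype. The control came from hnRNPK flox/flox mice and the knockout from hnRNPK flox/flox mice that also carry Alb-Cre, the Cre recombinase under the albumin promoter, which is active in hepatocytes. These groups follow the sample labels. The series title instead calls the control wild type and the knockout hnRNPK-MKO, an abbreviation it does not spell out, and this difference could not be settled here. Per the labels' protocols, RNA was taken up in Trizol and libraries followed a Lifetech protocol, and the design text names an Illumina NovaSeq instrument. Sex, age, and the number of mice behind each library are not given in the sources used here.

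The authors deposited 1 gene table with a whole-number read count and an FPKM value (a read count scaled by gene length and by the library's counted reads) for each of 21936 genes and both libraries. Per the submitters' processing notes, Bowtie2 2.4.2 and the mm10 mouse genome were used. The counting program, the annotation, the treatment of reads that match several places, and the strand setting are not given in the sources used here. Each deposited FPKM value was recomputed from the deposited count, gene length and column total, and all 21936 genes matched in both libraries within a relative tolerance of 1e-06. Gene coordinates were set beside the GENCODE annotation of the same genome build: 21817 gene identifiers were shared and 21617 had identical coordinates. Symbols carried by more than 1 identifier (31 symbols) were left as separate genes.

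Everything else was computed from the counts with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Library totals were multiplied by TMM factors from edgeR 4.0.16 in R 4.3.3, and these were 1.004 for the control and 0.996 for the knockout. DESeq2 1.42.0 gave the median-of-ratios size factors for an alternative scaling. The log2 ratio of knockout over control used scaled counts with 0.5 added to each library. Folds were ratios of scaled counts with nothing added, with an exact Clopper-Pearson 95% interval from the split of a gene's reads between the libraries. These intervals and the floors for counts of 0 cover counting error only, since reads without molecular identifiers are not independent molecules. A fold against a library with 0 reads was set against a floor of 3 counts in that library and is given as a lower bound.

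With 1 library per genotype no test across samples could be made, so no p-value is given and no difference has a replicate check. The values compare these 2 libraries, and differences between mice, dissected pieces or library preparations are included in them. A size rule took the place of a test. A gene was evaluated when its higher library reached FPKM 1 and 20 counts, and it was past the rule when the ratio was at least 2 or at most 0.5. The size rule, 25 gene lists, 11 lists of cell type or carry-over markers, the named genes and most alternatives were fixed before the data were examined. A list's median log2 ratio was set against the medians of 10000 random lists of the same size drawn from evaluated genes in 20 bins of mean expression, as a description of these libraries. Genes of a list are not independent replicates. Several lists share members, among them Spp1, which is in the ductular and matrix lists, and Col1a1 and Col3a1, which are in the fibroblast and matrix lists.

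Named genes followed a fixed rule. It took Hnrnpk, the 12 largest and 12 smallest log2 ratios among evaluated genes with FPKM 5 or more in the higher library, and up to 4 members of each list with the largest differences. It also took the least different member of each list and the 5 highest levels per library, and left out symbols of predicted genes. Some genes that the rule takes are not reported here. Genes outside this rule are marked as chosen after their values were seen, and other members of a list appear only where a group is described. Exceptions without such a mark are Rmi1, mt-Co2, mt-Co3 and mt-Atp6, which are also outside the rule. Alternatives covered scaling, unit, pseudocount, expression filter and fold threshold. Corrections for gene length and for length with GC content subtracted the running median of the log2 ratio over 401 genes, and 12 gene families were added, all after the data were seen. GC content was known for 9559 of the 9563 evaluated genes.

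The calculation was tested on simulated counts drawn from the 2 libraries' means and totals. The rule recovered 92 of 92 evaluated genes given a 4-fold difference and 91 of 92 given a 3-fold difference. Changed genes were drawn only from genes above a minimum mean count, so this recovery does not cover the lowest counts. No variation between mice or preparations was simulated. Counting error alone put 6 of 9264 unchanged genes past it. Genes of near-identical families, such as the major urinary proteins, and genes that overlap a neighbour are uncertain, because the sources used here do not say how shared reads were counted.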

Results

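Liver RNA from 1 control library (hnRNPK flox/flox) and 1 knockout library (hnRNPK flox/flox Alb-Cre) was compared to ask how liver gene expression differs when Hnrnpk is deleted by Cre under the albumin promoter. Hnrnpk encodes heterogeneous nuclear ribonucleoprotein K, an RNA- and DNA-binding protein. The table held 12428975 counted reads for the control and 12176239 for the knockout. There were no replicates, so each fold below carries a 95% interval for counting error only. Both libraries were dominated by hepatocyte transcripts. Alb, which encodes serum albumin, took 7.50% of control and 7.46% of knockout reads. The 10 most abundant genes together took 19.2% and 19.7%. The highest levels were those of Alb (FPKM 32028 in the control and 31832 in the knockout), mt-Co1 (17725 and 15717), Mup7 (10271 and 9434), mt-Cytb (8738 and 7168), Apoe (8509 and 10867) and Serpina1e (6502 and 8844). The mitochondrial genes mt-Co2, mt-Co3 and mt-Atp6 had 963, 508 and 346 control reads beside 340367 for mt-Co1. How reads that match several genomic places were counted is not given in the sources used here, so mitochondrial levels and their rank are uncertain. Across genes, the 2 libraries' log counts had a Spearman correlation of 0.976, with genes not being independent replicates.

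Hnrnpk itself (ENSMUSG00000021546, mm10 chromosome 13, 58391142 to 58403343, minus strand) had 2559 reads in the control and 1411 in the knockout, or FPKM 31.8 and 17.9. The knockout level was 0.567 of the control level (95% interval 0.531 to 0.605), a log2 ratio of -0.82 that stayed short of the 2-fold rule. The gene's 5' end overlaps Rmi1, which lies on the opposite strand, over 1096 bases, and Rmi1 had 190 and 108 reads. Reads of these genes cannot be told apart there without strand information. Counts over whole genes do not show which exons lost reads. Among 28 evaluated hnRNP and related RNA-binding protein genes, 0 passed the size rule and the median log2 ratio was -0.10, or -0.02 after a correction for gene length. The largest differences in that list were those of Hnrnpa1 (915 and 578 reads, log2 ratio -0.62), Ptbp2 (0.54) and Pcbp4 (-0.48), while Hnrnph1 was at 0.00.

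Of 9563 evaluated genes, 237 were at least 2-fold higher in the knockout and 106 at least 2-fold lower, together 3.59%. The counting interval of 341 of these 343 genes excluded a ratio of 1. The highest ratio among well-expressed genes belonged to Dmbt1, a mucin-like epithelial gene, with 2 control and 664 knockout reads (341-fold, 94.2 to 2826). It was followed by Tff3, which encodes a trefoil peptide of mucous epithelia (6 and 77 reads, 13.2-fold, 5.80 to 37.1), and Cd24a, a surface protein of progenitor and ductular cells (15 and 171 reads, 11.7-fold, 6.91 to 21.4). Rtl8c, with 3 and 25 reads, had a wide interval (8.57-fold, 2.62 to 44.4). Spp1, the gene of the secreted matrix protein osteopontin, was 5.44-fold higher (4.68 to 6.34). Cyp26a1, an enzyme that degrades retinoic acid, was 5.23-fold higher (4.64 to 5.91). Ccnd1, which encodes the cell cycle protein cyclin D1, was 5.18-fold higher (4.18 to 6.49). Gstm3, a glutathione S-transferase, was 5.06-fold and Tubb2a, a beta tubulin, 4.55-fold higher. This top group also held the major urinary protein genes Mup9 (6.50-fold) and Mup19 (4.20-fold), whose near-identical copies share sequence, so the assignment of reads to single copies is uncertain.

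In the other direction, Serpine2, which encodes a serine protease inhibitor, had 593 control and 83 knockout reads, 6.95 times as high in the control. Rgs16, a regulator of G protein signalling, was 5.42 times as high in the control, the glutamate transporter gene Slc17a8 5.05 times and Cyp2c40 4.60 times. Hcn3, which encodes an ion channel, followed with 3.52 times, Fitm1, a lipid droplet protein gene, with 3.22 times, and Fam107a with 2.94 times. Ppp1r3c, which targets protein phosphatase 1 to glycogen, had 2701 and 1011 reads (2.60 times). Cyp2c37 had 5927 and 2300 reads (2.51 times), the coagulation factor VII gene F7 1342 and 522 (2.50 times), and Slc35e3 416 and 166 (2.44 times). Ppara, the nuclear receptor that controls fatty acid oxidation genes, had 1995 and 777 reads (2.50 times).

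**Figure D1:**
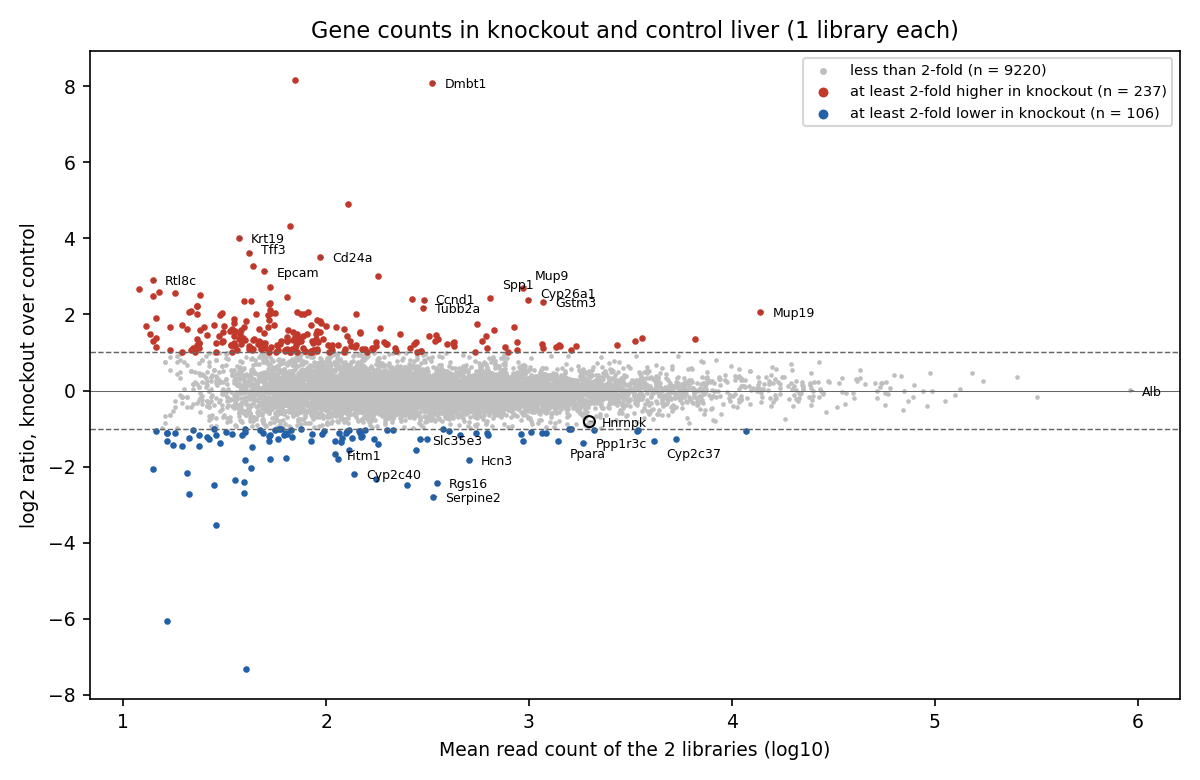
Log2 ratio of knockout over control liver (y axis) against the log10 mean read count of the 2 libraries (x axis) for the 9563 evaluated genes, with genes at least 2-fold higher in red (237), at least 2-fold lower in blue (106), the others in grey (9220), dashed lines at 2-fold and Hnrnpk circled. Genes past the rule were most frequent at low counts, and 3 genes with 0 reads in 1 library are drawn at a position set by the 0.5 added to each count.

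Markers of cholangiocytes and ductular cells, the epithelium of bile ducts, were higher in the knockout library. Of 7 evaluated members, 5 were past the size rule and 0 were lower, with a median log2 ratio of 2.44 that 0 of 10000 random lists reached. Krt19, a keratin of biliary epithelium, had 4 and 70 reads (18.0-fold, 6.72 to 67.9), and the epithelial adhesion gene Epcam 10 and 89 reads (9.15-fold, 4.75 to 19.7). Cd24a and Spp1 were described above, and Bicc1 had 40 and 98 reads. Sox9, a transcription factor of biliary cells, stayed within the rule (log2 ratio 0.60). The list of fetal liver and tumour-associated genes had 6 of 11 evaluated members higher and 0 lower, with a median of 1.31 (0 of 10000 random lists). It shares Epcam with the ductular list. Its other leading members were Tspan8 (7 and 41 reads), Afp, the gene of alpha-fetoprotein (20 and 86 reads, 4.42-fold, 2.69 to 7.60), and Ly6d (8 and 35 reads), while Aldoa was at 0.05. The lowest evaluated member was at -0.70. Most of the 26 listed genes were below the expression minimum. Of the 9 of these with 10 or more reads in total, 6 had a log2 ratio above 0 and 3 below. The latter were Hk2 (28 and 13 reads), Igf2bp2 (16 and 9) and Mycn (11 and 8). Igf2, Dlk1, Lin28b and Igf2bp1 had 0 reads in both libraries.

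Extracellular matrix genes were also higher, with 10 of 20 evaluated members past the rule, 0 lower, and a median log2 ratio of 1.07 (0 of 10000 random lists). Beside Spp1, these included the matrix gene Dpt (32 and 131 reads, 4.21-fold, 2.84 to 6.41), the collagen cross-linking enzyme Loxl1 (12 and 49 reads) and Col15a1 (21 and 82 reads). The fibrillar collagen genes Col1a1 (48 and 152 reads, 3.26-fold, 2.34 to 4.61) and Col3a1 (189 and 505 reads, 2.75-fold, 2.32 to 3.27) were past the rule as well. The abundant Fn1, which hepatocytes also express, was at -0.31 and Tgfb1 at 0.13. Of 12 evaluated markers of hepatic stellate cells and fibroblasts, 3 were higher and 0 lower, with a median of 0.42 (5 of 10000 random lists). Col1a1 and Col3a1 are on both lists, Cygb was 2.04-fold higher (1.47 to 2.86), Acta2 had 50 and 97 reads, just within the rule, Reln was at -0.18 and Ecm1 at -0.36 (1384 and 1048 reads).

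Macrophage, endothelial and lymphocyte markers had medians nearer 0. Of 13 Kupffer cell and macrophage markers, 1 was higher (Cd9, 70 and 183 reads) and 1 lower (Timd4, a marker of resident Kupffer cells, 74 and 32 reads), with a median of -0.09 and C1qc at 0.09. The median was -0.24 after the length correction, and 65 of 10000 random lists were then as low. The 4 members below the expression minimum, which mark infiltrating or activated macrophages, all had more knockout reads: Trem2 (3 and 25), Ccr2 (9 and 37), Cx3cr1 (7 and 25) and Gpnmb (3 and 10). None of 13 sinusoidal endothelial markers passed the rule, and their median was -0.11, with Stab1 at -0.51 and Lyve1 at -0.50. The 3 evaluated B and plasma cell markers, which include the antigen presentation genes Cd74 and H2-Aa, had a median of -0.07 (-0.17 after the length correction), and 0 neutrophil and 0 T or NK cell markers were expressed highly enough to be evaluated. Erythroid genes had a median of 0.79 over 6 members (1 of 10000 random lists as high), with 1 past the rule (Hbb-bt, 106 and 248 reads) and Hbb-bs at 911 and 1664 reads. Alas2, the member with the most reads, was at 0.11 (1797 and 1888), and the globin gene Hba-a2 at -0.67 (20 and 12). Of 3 adipose genes, Cfd (8 and 21 reads) was higher, Cidec (132 and 58) lower and Fabp4 within the rule, with a median of 0.47 inside the central range of random lists. The adipocyte genes Adipoq and Plin1, below the minimum, each had 0 control and 6 knockout reads. The pancreatic list had 1 evaluated gene, Cela1 (-0.48), and the gut and gall bladder list 1, Fabp2 (-0.46). Below the minimum, 3 other gut and gall bladder genes had reads almost only in the knockout library: Tff2 (0 and 14), Vil1 (1 and 25) and Gkn3 (1 and 13).

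**Figure D2:**
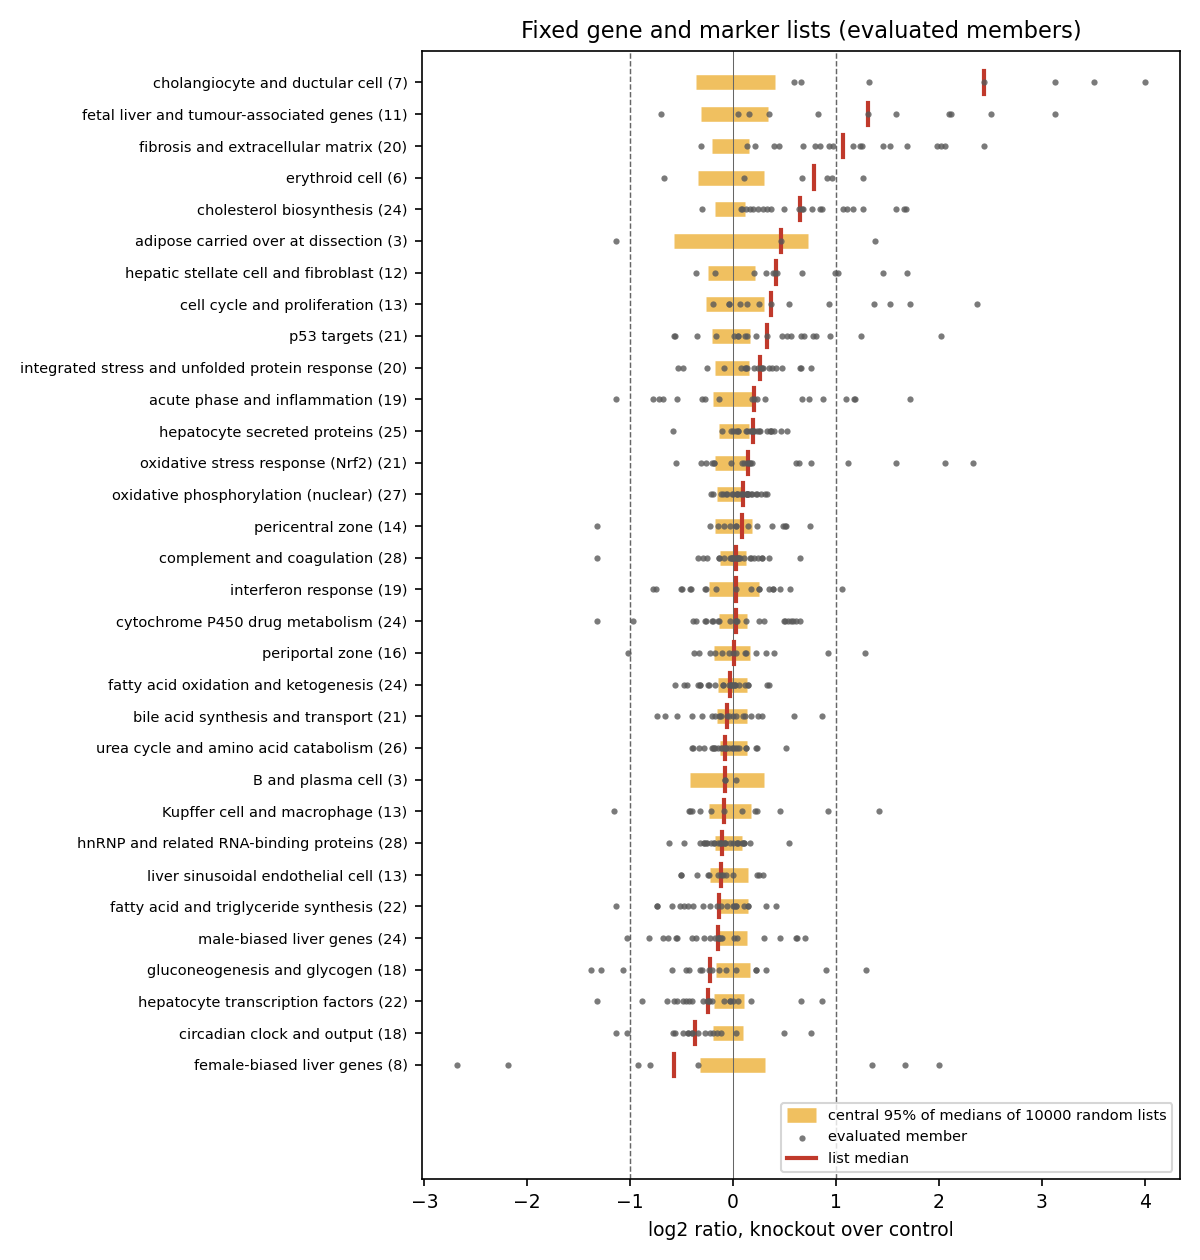
Log2 ratio of knockout over control for evaluated members (grey points) of each fixed list with 3 or more of them, with the list median (red line) and the central 95% of the medians of 10000 expression-matched random lists (orange bar). The number of evaluated members is in parentheses and dashed lines mark 2-fold. The ductular, fetal liver and matrix lists have medians of 2.44, 1.31 and 1.07, and the female-biased list has the lowest median, -0.57, with members on both sides of 0.

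Cholesterol biosynthesis genes were higher as a group. All 24 listed genes were evaluated, 7 were at least 2-fold higher and 0 lower, and the median log2 ratio was 0.66 (0 of 10000 random lists). The mevalonate and sterol pathway enzymes Mvd (54 and 169 reads, 3.22-fold, 2.36 to 4.46), Hmgcs1 (415 and 1274 reads, 3.16-fold, 2.82 to 3.54), Sqle (344 and 1006 reads, 3.01-fold, 2.66 to 3.41) and Idi1 (521 and 1219 reads, 2.41-fold, 2.17 to 2.67) led the group. Ebp was at 0.08, and Fdps, the 1 member below 0, at -0.30. Genes of fatty acid and triglyceride synthesis did not share this direction. Of 22, 1 was lower (Cidec, a lipid droplet protein gene, log2 ratio -1.14) and 0 higher, with a median of -0.14. Lpin1 (-0.74), G0s2 (-0.74) and Elovl6 (-0.59) were below 0 within the rule, and Fads2 was at 0.00. After the correction for gene length, this list's median was -0.04. No fatty acid oxidation gene of 24 passed the rule (median -0.03, or -0.09 after that correction). Acot1 was at -0.48, Acaa1b at -0.45 and Pdk4 at 0.35.

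Among 18 gluconeogenesis and glycogen genes, 3 were lower and 1 higher, with a median of -0.22 that 44 of 10000 random lists matched or fell below. Lower were 2 glycogen-targeting subunits of protein phosphatase 1, Ppp1r3c and Ppp1r3b (7613 and 3052 reads, log2 ratio -1.28), and Pklr, the liver pyruvate kinase (4650 and 2161 reads, -1.06). Igfbp1, an insulin-repressed secreted protein gene, was 2.45-fold higher (346 and 823 reads, 2.16 to 2.78), and Gckr was at 0.03. None of 26 urea cycle and amino acid catabolism genes passed the rule (median -0.07), with Glul, the pericentral glutamine synthetase, at 0.52 and Gldc at -0.40. No bile acid gene of 21 passed it either (median -0.06). The bile acid synthesis enzymes Cyp8b1 (1250 and 730 reads, -0.73) and Cyp7a1 (3717 and 2285 reads, -0.66) were below 0. Nr0b2, a nuclear receptor that represses bile acid synthesis, was at 0.86, and the canalicular phospholipid transporter Abcb4 at 0.59. For nuclear oxidative phosphorylation genes, 0 of 27 passed the rule, and the median of 0.10 became 0.01 after the length correction.

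Genes of hepatocyte secretion and identity were mostly within 2-fold. None of 25 secreted protein genes passed the rule, with a median of 0.19 (47 of 10000 random lists as high). It was 0.13 after the length correction (334 of 10000) and 0.10 with GC content corrected too (990 of 10000). Apoa1 was at 0.47, Ahsg at 0.40, Serpina1a at 0.53 and Serpina1c at -0.58, the last 2 being near-identical copies. Of 28 complement and coagulation genes, 1 was lower (F7, log2 ratio -1.32), the median was 0.03 and Mbl2 was at 0.65. Of 24 cytochrome P450 and drug metabolism genes, 1 was lower (Cyp2c37, -1.32), with Cyp2b10 at -0.97 just within the rule, Cyp2d10 at 0.65, Cyp2e1 at -0.03 and a median of 0.03 that was -0.06 after the length correction. The hepatocyte transcription factor list had a median of -0.24, and 22 of 10000 random lists were as low. Of its 22 members, 1 was lower (Ppara, -1.32), Prox1 had 2019 and 1066 reads (-0.88) and Foxa1 was at 0.00. The markers of liver zones showed no common direction. Pericentral genes had 1 of 14 lower and a median of 0.09, with Gulo at 0.75 and Cyp1a2 at 0.51. Periportal genes had 1 of 16 higher (Cdh1, the gene of E-cadherin, 254 and 602 reads) and 1 lower (Etnppl, 2185 and 1046 reads), with a median of 0.01.

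Of 21 evaluated p53 target genes, 2 were higher and 0 lower, with a median of 0.33 (1 of 10000 random lists). These were Gdf15, which encodes a stress-induced secreted factor (30 and 120 reads, 4.11-fold, 2.74 to 6.36), and Phlda3 (14 and 33 reads, 2.42-fold, 1.26 to 4.90). Btg2 (0.94), Ddb2 (0.81) and Cdkn1a, the cell cycle inhibitor p21 (0.78), were within the rule, and Mdm2 and Bbc3 were at 0.05 and 0.01. Another 4 of the 21 were below 0, the lowest at -0.57. Summed over all listed p53 targets, the reads were 8165 and 8280 (log2 ratio 0.06). Of 6 members below the expression minimum with 10 or more reads in total, 3 were higher and 3 lower. In the cell cycle list, 4 of 13 evaluated genes were higher and 0 lower (median 0.37, 73 of 10000 random lists). They were Ccnd1, Cdc20 (9 and 30 reads), the replication helicase subunit gene Mcm6 (36 and 102 reads) and Ccne1 (22 and 56 reads), while Mcm4 was at -0.04. Another 19 of the 32 listed genes were below the expression minimum. Of the 18 of these with 10 or more reads in total, 14 had a log2 ratio above 0 and 4 below, with Mki67 at 27 and 66 reads, Top2a at 10 and 39, Ccnb1 at 5 and 17, and Mcm2 at 48 and 32.

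None of 20 integrated stress and unfolded protein response genes passed the rule, and the median was 0.26 (10 of 10000 random lists as high). It was 0.16 after the length correction (192 of 10000) and 0.14 with GC content corrected too (343 of 10000). Atf5 (0.76), Sesn2 (0.66) and Manf (0.65) were the highest, and Chac1 was at -0.54. Of 21 oxidative stress response genes, 4 were higher, namely Gstm3, Gsta1 (8 and 34 reads), the carbonyl reductase gene Cbr3 (12 and 36 reads) and Gsta2 (398 and 839 reads), with a list median of 0.15 and Gclm at -0.02. Gsta1 and Gsta2 are close copies whose shared reads are uncertain. Acute phase and inflammation genes had 4 of 19 higher and 1 lower, with a median of 0.21 (129 of 10000 random lists as high). After the length correction it was 0.11 (1023 of 10000), and 0.07 with GC content corrected too. The adhesion gene Icam1 (40 and 129 reads, 3.32-fold, 2.31 to 4.86), Orm3 (log2 ratio 1.19) and Lcn2 (1.18) were higher, and the chemokine gene Cxcl1 (48 and 21 reads) was lower. Interferon response genes had 1 of 19 higher (Ifi27l2a, 14 and 29 reads) and a median of 0.03, with Rsad2 at -0.78 and Ifit1 at -0.75.

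The 8 evaluated female-biased liver genes went both ways, with 3 higher, 2 lower and a median of -0.57 (9 of 10000 random lists as low). Lower were Cyp2c69 (69 and 10 reads, log2 ratio -2.69) and Cyp2c40 (-2.19), which belong to a family of similar copies. Higher were the steroid hydroxylase gene Cyp17a1 (57 and 223 reads, 4.02-fold), Atp6v0d2 (19 and 60 reads, 3.25-fold) and the estrogen sulfotransferase gene Sult1e1 (log2 ratio 1.35). Of 24 male-biased genes, 1 was lower (Mup21, 4663 and 2221 reads, -1.03) and 0 higher, with Mup1 at -0.82, Cyp2d9 at 0.70, Cyp4a12b at 0.01 and a median of -0.14 (293 of 10000 random lists as low). After the length correction that median was -0.23 (2 of 10000). The Y-linked gene Ddx3y had 1117 control and 740 knockout reads. Circadian clock and output genes had a median of -0.37, which 0 of 10000 random lists fell to. Of 18, 2 were lower and 0 higher, with the repressor gene Nfil3 (269 and 128 reads, log2 ratio -1.03) among the lower ones. Usp2 was at -0.58, Nr1d1 at 0.76 and Nr1d2 at 0.03. Times of day of collection are not given in the sources used here.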

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

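Corrections for gene length, with or without GC content, were chosen after the data were seen, and the other alternatives before. Under library totals alone, median-of-ratios size factors, totals without the 20 most abundant genes, a median log2 ratio set to 0, pseudocounts of 0.1 and 1, both corrections and the omission of predicted genes, the count of higher genes ranged from 219 to 253 and that of lower genes from 96 to 111. Length correction left 221 higher and 104 lower, of which 209 and 91 were past the rule without it. Counts moved by over 1.5 times under the settings that follow, as higher and lower genes: deposited FPKM with 0.5 added, 135 and 52; no expression filter, 1865 and 988; FPKM 5 or more in the higher library, 71 and 34; a 1.5-fold threshold, 588 and 506; a 4-fold threshold, 44 and 16; and only genes whose counting interval excludes 2-fold, 91 and 32. The threshold and filter settings change these counts by construction, and 0.5 added to FPKM shrinks ratios of low genes. Of the genes past the rule, 69.1% were higher, and 53.7% at 1.5-fold. The Hnrnpk log2 ratio of -0.82 was -0.72 under the length and GC correction, outside its counting interval, and the cause was not tested. For named genes, 1424 of 1539 alternative values stayed within the counting interval, 115 moved beyond it and 0 reversed. List and family medians were classed as the same, though not always identical, in 453 of 480 alternatives, and as moved in 27. The medians of the Kupffer cell, cytochrome P450, interferon, periportal and histocompatibility sets, all near 0, changed sign under at least 1 setting. Genes past the rule were most frequent at low counts: the 2398 evaluated genes with the lowest counts (20 to 153 reads) held 162 higher and 55 lower genes, against 26 and 19 among the 2389 with the highest. Depth limits the precision of single ratios, as in Rtl8c with 3 and 25 reads (2.62 to 44.4), but counting error alone put 6 of 9264 simulated unchanged genes past the rule, and no other cause of the excess was tested. No paired analysis was possible because each genotype had 1 library. The table lists genes, so the transcript setting was not run, and no replicate could be left out.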

Other observations

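The gene families and single genes of this part, the 3 tests on ductular, endothelial and gut markers, the test on major urinary protein copies and the use of random lists to judge length-corrected medians were chosen after the values were seen. Genes of retinoic acid turnover and response stood out, with 4 of 7 evaluated members higher and 0 lower, and a median log2 ratio of 1.62. The retinoic acid hydroxylase genes Cyp26b1 (40 and 319 reads, log2 ratio 3.02) and Cyp26c1 (17 and 52 reads, 1.62) were higher beside Cyp26a1. The choice of this family was prompted by members among the 12 highest ratios. Tgm2 was at 0.54, Lrat, a stellate cell enzyme of retinol storage, at 0.32 and Dhrs3 at 0.16, and of 2 members below the expression minimum, the retinoic acid receptor gene Rarb had 13 and 27 reads and Aldh1a3 17 and 8. Of 9 evaluated tubulin genes 2 were higher, Tubb2a and Tuba8 (8 and 79 reads, log2 ratio 3.26), with a median of 0.65. The hepatocyte keratin gene Krt18 (902 and 1957 reads, 1.16) was past the rule and its partner Krt8 (1626 and 2910 reads, 0.88) within it. The 4 evaluated keratins, which include the ductular marker Krt19 (log2 ratio 4.01), had a median of 1.02, with the lowest at -0.29. Glutathione S-transferases had 4 of 14 higher (median 0.41), UDP-glucuronosyltransferases of the 2b family 1 of 7 (0.49) and sulfotransferases 1 of 8 (0.56). Carboxylesterases (median -0.15, or -0.23 after the length correction), histocompatibility genes (-0.10 or -0.17) and mitochondrially encoded genes (-0.16 or -0.27) had 0 members past the rule.

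Gldn, with 0 control and 140 knockout reads, was at least 48.0-fold higher, against a floor of 3 counts in the control. Acta1, the skeletal muscle actin gene, had 81 control and 0 knockout reads (at least 26.3-fold lower), and Tnnt3, a skeletal troponin gene, 33 and 0 (at least 10.7-fold lower). Of 15 skeletal muscle genes examined for this reason, 10 had reads in the control and 0 in the knockout, among them Myh4 with 65 reads, Myh2 with 34, Atp2a1 with 32 and Ckm with 18. Another 4 had reads in both libraries, namely Tpm2 (45 and 40), Tnnc1 (23 and 10), Tnni2 (16 and 2) and Mylpf (13 and 5). Muscle tissue carried into the control piece was not ruled out as the origin of these reads, so they are not read as a difference in liver cells. Near Hnrnpk on chromosome 13, Idnk (226449 bases away) had 293 and 171 reads, log2 ratio -0.73. Ntrk2, which encodes a neurotrophin receptor 403226 bases away, had 8 and 248 reads (31.9-fold higher, 15.9 to 74.7). The other 5 evaluated genes within 1 Mb that do not overlap Hnrnpk had log2 ratios between -0.36 and 0.11.

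Several list medians stood apart from random lists, while the log2 ratio also followed gene length, with a Spearman correlation across genes of -0.27 and decile medians from 0.13 for the shortest to -0.16 for the longest genes. For the ductular, matrix and cholesterol lists the trend is argued against as the whole cause, because the smallest of their medians was 0.655 after the length correction and 0.621 after the correction for length and GC content. The hepatocyte transcription factor list had a median of -0.24, which was -0.230 after the length correction, with 3 of 10000 random lists as low. That median passed the bound set for arguing against length. Its resampled 95% range (-0.45 to -0.05) reached into the values set for length as the cause. Length as the whole cause was therefore left undecided for this list. The 76 evaluated ribosomal protein genes, of which 71 were above 0 and 0 past the rule, had a median of 0.28. It became 0.187 after the length correction (0.144 to 0.243, 0 of 10000 random lists as high), so length may account for part of it. That median fell short of the bound set for arguing against length, so length as the whole cause was left undecided for these genes. Differences between mice, and genotype itself, stay open with 1 library each.

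Ductular and, to a lesser degree, fibroblast markers were higher in the knockout library. A lower share of hepatocytes would raise the markers of every other cell type alike, but the ductular median exceeded the sinusoidal endothelial median by 2.55 on the log2 scale, and no endothelial marker reached the ductular median. All 12 of 12 ductular markers with 10 or more reads in total were higher, Krt7 (10 and 33 reads) and Muc1 (6 and 27) among them. Of 4 gall bladder and gut genes with as many reads, 3 were higher (Tff2, Vil1 and Gkn3, with 14, 25 and 13 knockout reads), and the one that was lower, Fabp2, had 531 control reads. A piece with more ducts and portal tissue, gall bladder or gut epithelium carried over, an expansion of ductular cells, or expression of these genes in hepatocytes after Hnrnpk loss might each give this, and 1 library per genotype leaves them open.

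Major urinary protein genes differed between copies, with 7 of 20 evaluated genes higher and 1 lower. Reads shared between near-identical copies and divided differently could give opposite shifts that cancel in the sum. Over the 16 copies that share at least 50% of their 50-base stretches with another, the sum went from 212042 to 251990 reads, a log2 ratio of 0.290 (0.281 to 0.298), with 58096 scaled reads gained by some copies and 10955 lost by others, and 6 copies were past 2-fold higher and 0 past 2-fold lower. The remaining 6 genes, among them Mup21, the one past 2-fold lower, had 130451 and 97024 reads (log2 ratio -0.39), and all 22 together 342493 and 349014 (0.07). Divided reads as the whole cause are neither excluded nor shown by these sums, and a difference between mice or genotypes stays open.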
